A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

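Budding yeast (Saccharomyces cerevisiae) RNA was measured on 5 two-colour arrays with a spot for nearly every open reading frame (ORF). Per the labels and the study's design text, overnight cultures in rich YP medium with 2% glucose were diluted to an OD600 of 0.1 in YP with 2% or 20% glucose and collected after 1 hour. Each array carried RNA of both media, reverse transcribed with aminoallyl nucleotides and coupled to Cy5 or Cy3. Arrays 1, 3 and 4 have 2% glucose in Cy5 and arrays 2 and 5 have 20% glucose in Cy5, per the labels. The arrays were used as the replicates. The labels do not say whether they come from separate cultures or from dye swaps of shared RNA, so the p-values measure only the spread between these arrays, which may be technical.

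The deposited table holds log2 ratios of the channels, normalized within each array to a median near 0 (medians from 0.00 to 0.01 after the repair described below); the software the authors used is not given in the sources used here. For arrays 4 and 5 the deposited scanner files were also used. Per the file headers these hold the intensity of each spot and of its local background at both wavelengths as medians, a log2 ratio, a log2 ratio shifted by 1 constant per array (0.04 on array 4 and 0.29 on array 5), and a flag, a quality score per spot. Scanner files of arrays 1 to 3 were not used here. No filter that the authors applied is named in the files. Of the table's 6298 rows, 80 are control rows with no value and 6218 are spots of 6205 ORFs, 13 of which have 2 spots that were averaged. The arrays hold 5669, 5373, 5650, 5804 and 5568 values in the order 1 to 5. The 17 flagged spots of array 4 and the 47 of array 5 have no value in the table.

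The table of arrays 4 and 5 carries a decimal slip. On array 4, 258 deposited values, and on array 5, 262, are 10 or more in size, reaching 70.8 in the deposited table, and their median multiple of the scanner ratio is 10.4 on array 4 and 8.91 on array 5. These values were divided by 10. After this the correlation across spots with the scanner ratios was 0.991 on array 4 and 0.964 on array 5, against 0.775 and 0.770 as deposited. Arrays 1 to 3 hold no value of that size. Set against the scanner files, the sign of the table is Cy5 over Cy3 on array 4 and Cy3 over Cy5 on array 5, which by the dye labels is 2% over 20% glucose on both. All values were multiplied by -1 to give log2 of the RNA labelled 20% over the RNA labelled 2% glucose. Scale and direction of arrays 1 to 3 could not be set against scanner values; they were taken to be those of the other columns.

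The median intensity minus background was 1324 (Cy5) and 1269 (Cy3) on array 4 and 695 and 593 on array 5. Spot over background had a median of 15.9 and 12.1 on array 4 and of 13.3 and 10.1 on array 5. On array 5, 1 spot was saturated in Cy5. The number of arrays limits the precision.

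Ratios were fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a term for the glucose label and a term for the dye, for the 5447 ORFs with a value on at least 4 arrays, which hold both dye orientations. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was 0.05. The fit has 3 residual degrees of freedom per gene with all 5 values. Shifts of 26 gene lists, written before the data were examined, were tested with limma's camera with a preset correlation of 0.01 on the 4693 genes with all 5 values, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. The difference between arrays 1 to 3 and arrays 4 and 5, a split planned because scanner files exist for the latter, was tested with a further term in the same fit. Within arrays 1 to 3 the fit kept the dye term, and within arrays 4 and 5 it had none. Each of these within-set fits has 1 residual degree of freedom, so its p-values lean on the spread shared over genes.

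Named genes are the 12 highest and the 12 lowest log2 changes among genes past the threshold with the same sign on every array, 18 genes fixed before the data were examined, and up to 4 members with the smallest p of each list described. Genes named outside this rule are said to be chosen after their values were seen. ORF identifiers were paired with names through a RefSeq gene table (assembly R64), which matched 5705 of 6205. The other 500 kept their identifiers and were counted but not named. The arrays name no genome build, so no positions are given. Spots may not separate overlapping genes, and near-identical copies such as HXT6 and HXT7 may share signal.

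The procedure was tested on simulated data: among 5447 genes with the real residual spread, 200 of them changed, the 5-array fit recovered 22.5% at a log2 change of 0.5, 77% at 1 and 94% at 2, with 3, 4 and 6 false calls. With no change it made 0 calls. With a spread taken from arrays 4 and 5 it recovered 100% at each of these sizes, with 16, 13 and 13 false calls. The simulated errors were independent between arrays, without the sets into which the real arrays fall. The simulation therefore does not show how many false calls the real data give. Alternatives left out the dye term, an array at a time or genes with missing values, centred or scaled the arrays, weighted arrays, changed the moderation, and used the scanner intensities of arrays 4 and 5 (normexp background correction with offset 50 and loess, no background subtraction, or without spots under 2 times background in both channels). Other alternatives fitted each set or dye orientation alone, used 1 spot per gene, or applied stricter thresholds. After the data were seen, the table without the decimal repair, arrays 4 and 5 averaged as 1 replicate, and exchanged dye labels were added. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.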

Results

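The study asked how yeast transcription responds in the first hour after transfer to a medium with a high glucose concentration. Each of 5 arrays compared RNA of cells 1 hour after dilution into 20% glucose with RNA of cells diluted into 2% glucose, with 20% in Cy3 on 3 arrays and in Cy5 on 2. All log2 values below are RNA labelled 20% over RNA labelled 2% glucose, estimated over the 5 arrays with the standard error (SE) of the limma fit unless arrays are named.

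By the dye labels, several genes known for their response to high osmolarity and high glucose ran opposite to their known direction. GPD1, the glycerol 3-phosphate dehydrogenase induced in osmostress, was at -3.96 ± 0.97 (adjusted p = 0.0733) and was lower in the RNA labelled 20% on 5 of 5 arrays. GPP2, the glycerol 3-phosphatase of the same pathway, was at -2.33 ± 0.38 (adjusted p = 0.043). HXT1, the low-affinity hexose transporter induced by high glucose, was at -2.54 ± 0.26 (adjusted p = 0.0294). On array 5 its spot under the 20% label was less than 2 times background. HXT2, a high-affinity transporter repressed by high glucose, was at 2.26 ± 0.15 (adjusted p = 0.00924). The design text would predict the opposite signs. In the deposited values, before they were multiplied by -1 to follow the dye labels, GPD1, GPP2, HXT1 and HXT2 have the predicted signs. The direction used here rests on the dye labels alone, so the samples are called "RNA labelled 20%" and "RNA labelled 2%" throughout. If the dye labels are exchanged, every sign below turns.

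Over all 5 arrays, 122 genes were higher and 79 lower in the RNA labelled 20% glucose, of 5447 tested, and all 201 had the same sign on every array with a value. After HXT2 came NCE103, the carbonic anhydrase (2.13 ± 0.35, 4.38-fold), ARG4 of arginine synthesis (2.08 ± 0.37), CIT1, the mitochondrial citrate synthase (1.96 ± 0.27, 3.89-fold), and GAP1, the general amino acid permease (1.80 ± 0.15). They were followed by SPL2 of the phosphate response (1.77 ± 0.28), HIS4 of histidine synthesis (1.68 ± 0.24), the proline oxidase PUT1 (1.68 ± 0.19) and the mitochondrial porin POR1 (1.66 ± 0.19). CIT2, the peroxisomal citrate synthase, was at 1.53 ± 0.22, GGC1, the mitochondrial GTP/GDP carrier, at 1.51 ± 0.09 and WTM1, a nuclear protein, was 2.82-fold higher. The adjusted p of these 12 genes lay between 0.00924 and 0.044.

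The lowest after HXT1 and GPP2 (5.02-fold) were YHR033W (-1.99 ± 0.32), GAS2, a glucanosyltransferase of the spore wall (-1.76 ± 0.31), NQM1, a transaldolase paralog (-1.69 ± 0.08), and THI4 of thiamine synthesis (-1.62 ± 0.20). NCA3 (-1.56 ± 0.10), YOR062C (-1.41 ± 0.23), YML131W (-1.24 ± 0.10), YBR032W (-1.18 ± 0.11, on 4 arrays), FIT1, a cell wall protein of iron uptake (-1.17 ± 0.18), and the serine hydrolase FSH1 (-1.16 ± 0.21) completed the 12. NQM1 had the smallest SE of these 24 genes and lay between -1.79 and -1.60 on the arrays, with an adjusted p of 0.00539. A further 12 called ORFs have no name in the gene table used.

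**Figure D1:**
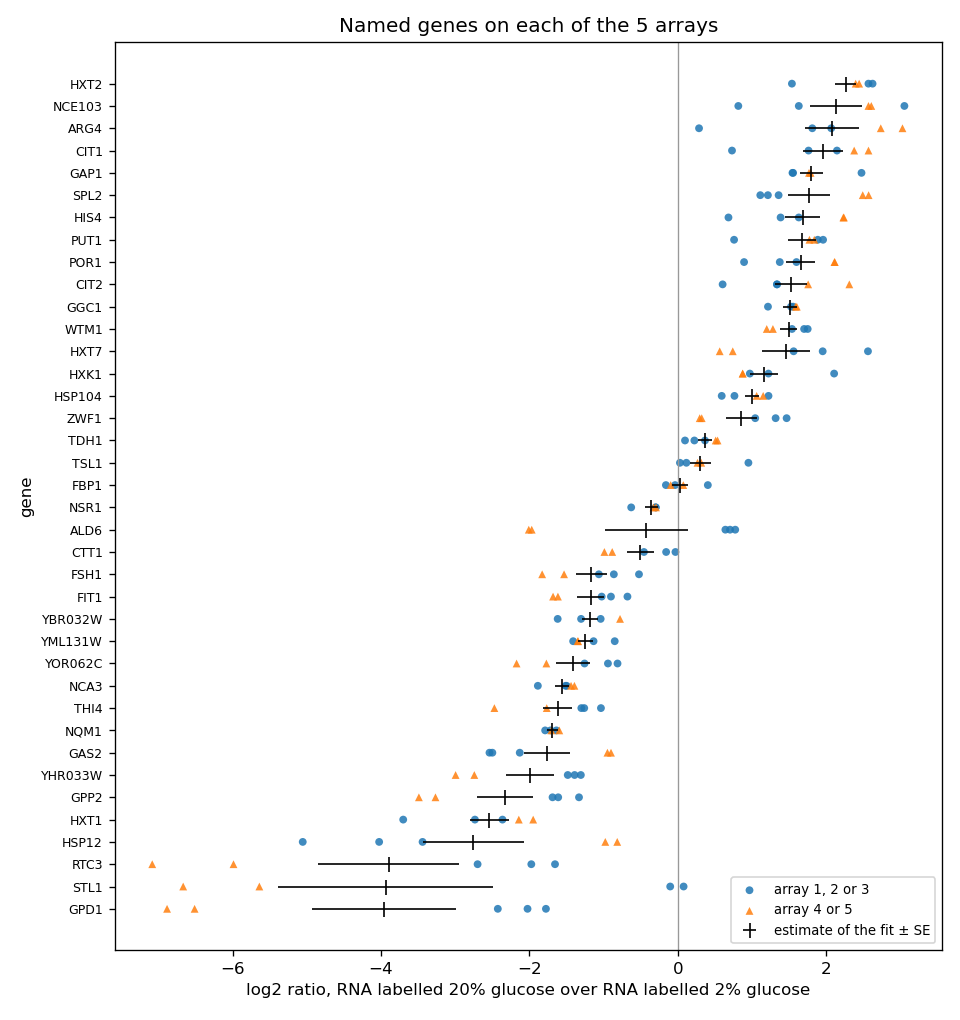
Log2 ratio of RNA labelled 20% over RNA labelled 2% glucose (horizontal axis) for each named gene (vertical axis) on arrays 1 to 3 (circles) and arrays 4 and 5 (triangles), with the estimate of the 5-array fit ± SE in black. NQM1 is even over the arrays, while GPD1 lies between -2.42 and -1.78 on arrays 1 to 3 and at -6.88 and -6.51 on arrays 4 and 5.

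These counts depend on all arrays being present: without replicate 1, 2, 3 or 5 the fit called 3, 1, 0 and 3 genes, and without replicate 4 it called 103. Without replicate 3, where limma called 0, 1096 genes had an unadjusted p under 0.05. The test of the dye effect called 0 genes in limma, with 18 at an unadjusted p under 0.05 where 272.35 are expected by chance, and 0 and 82 with the set of arrays as a term. So few small p-values mean that this test is too conservative to say whether the dye had an effect.

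Genes of ribosome synthesis were lower together in the RNA labelled 20%. Of 105 ribosome biogenesis genes tested, 0 had a positive estimate, 10 were lower past the threshold and 74 were lower when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 5.44e-23; adjusted p = 0.436 with an estimated correlation). NOP4 (-0.64 ± 0.09), NMD3, the export adapter of the large subunit (-0.55 ± 0.08), UTP23 (-0.58 ± 0.09) and DBP10 (-0.49 ± 0.08) had the smallest p. NSR1, the yeast nucleolin fixed beforehand, was at -0.36 ± 0.09 without passing (adjusted p = 0.0731). Of 20 RNA polymerase I and III genes, 2 were lower, RPA12 (-0.51 ± 0.07) and RRN3 (-0.47 ± 0.09), and 5 when adjusted over the list alone (median -0.25, camera adjusted p = 0.00011; adjusted p = 0.444 with an estimated correlation). The 39 translation factors had a median of -0.11 with 0 members past the threshold (camera adjusted p = 0.0235; adjusted p = 0.655 with an estimated correlation). The cytosolic ribosomal proteins had a median of -0.01 with 0 of 97 past the threshold (camera adjusted p = 0.726), a value between opposite shifts. They were lower on arrays 1 to 3 (median -0.13, camera adjusted p = 0.000568; adjusted p = 0.709 with an estimated correlation). They were higher on arrays 4 and 5 (0.17, camera adjusted p = 7.32e-05; adjusted p = 0.602 with an estimated correlation).

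Genes of mitochondrial energy metabolism were higher together. All 47 TCA cycle and respiration genes tested had positive estimates, 7 passed over all genes and 36 when adjusted over the list alone (median 0.75, camera adjusted p = 8e-16; adjusted p = 0.436 with an estimated correlation). Besides CIT1 the smallest p were those of KGD1 of the 2-oxoglutarate dehydrogenase (0.62 ± 0.09), the fumarase FUM1 (0.94 ± 0.14) and ATP4 of the ATP synthase (0.68 ± 0.11). In amino acid biosynthesis 9 of 64 genes were higher and 0 lower, or 25 and 3 when adjusted over the list alone (median 0.49, camera adjusted p = 8.79e-09; adjusted p = 0.444 with an estimated correlation). HIS4, ILV6 (0.71 ± 0.11), the glutamine synthetase GLN1 (1.19 ± 0.18) and TRP2 (0.64 ± 0.11) had the smallest p there. In glycolysis and fermentation 2 of 20 genes were higher, the alcohol dehydrogenase ADH1 (0.63 ± 0.08) and the hexokinase HXK1 (1.16 ± 0.19), or 15 higher and 1 lower when adjusted over the list alone (median 0.51, camera adjusted p = 4.43e-07; adjusted p = 0.436 with an estimated correlation). TDH1, a glyceraldehyde 3-phosphate dehydrogenase, was at 0.37 ± 0.09 without passing (adjusted p = 0.0799). In the gluconeogenesis and glucose-repressed list 3 of 19 genes were higher, ADH2 (0.71 ± 0.07), ICL2 (0.89 ± 0.11) and CIT2, or 5 when adjusted over the list alone (median 0.10, camera adjusted p = 0.043; adjusted p = 0.548 with an estimated correlation). FBP1, the fructose bisphosphatase, was at 0.02 ± 0.11.

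Stress genes went both ways. The osmostress and glycerol list did not pass as a whole (median -0.18 over 31 genes, camera adjusted p = 0.25). It mixes targets of the HOG kinase pathway with parts of the pathway itself, such as HOG1 and PBS2, and with further glycerol genes. Its median is therefore not that of the targets alone. GPD2 (0.79 ± 0.08) and HOR7 (0.85 ± 0.15) were higher and GPP2 lower past the threshold. In this list 5 were higher and 9 lower when adjusted over the list alone. STL1, the glycerol symporter (-3.93 ± 1.45, 4 arrays), HSP12, a membrane-protecting stress protein (-2.75 ± 0.69), and the catalase CTT1 (-0.50 ± 0.18) had adjusted p of 0.165, 0.0754 and 0.139. In the fit with the set of arrays as a term these were 0.000329, 0.00114 and 0.00749. That fit averages the sets, and STL1 was near 0 on arrays 1 and 3 (-0.10 and 0.08). RTC3 was lower on 5 of 5 arrays, with its spot under the 20% label near background on arrays 4 and 5. In the Msn2/Msn4 general stress list 4 of 30 genes were higher, among them the disaggregase HSP104 (1.00 ± 0.10), HXK1 and HOR7, and 1, DDR48, was lower (-0.83 ± 0.12), or 10 and 3 when adjusted over the list alone (median 0.31, camera adjusted p = 0.00913; adjusted p = 0.436 with an estimated correlation). Lists with smaller shifts past the camera threshold were heat shock proteins (median 0.15, 1 of 23 higher, adjusted p = 0.0146), oxidative stress defence (0.22, 2 of 23 with SOD2 and TSA1, adjusted p = 0.0213) and trehalose and glycogen (0.24, 1 of 21, the branching enzyme GLC3, adjusted p = 0.0333). With an estimated correlation their adjusted p = 0.444, 0.436 and 0.436. Adjusted over the list alone, 6 higher and 1 lower, 4 higher and 1 lower, and 1 higher passed in these. TSL1, a subunit of trehalose synthase, was at 0.31 ± 0.14 (adjusted p = 0.218).

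Sugar transport, nutrient and wall genes varied within their lists. In the hexose transport list HXT2 was higher and HXT1 lower of 19 genes, or 4 and 3 when adjusted over the list alone, without passing as a list (median 0.20, camera adjusted p = 0.277). HXT7, a high-affinity transporter whose spot can also take up HXT6, was at 1.46 ± 0.32 (adjusted p = 0.0626). Of the phosphate and iron regulons, the phosphate transporter PHO84 (1.12 ± 0.12) and SPL2 were higher and FIT1 lower of 24 genes, or 13 and 1 when adjusted over the list alone (median 0.72, camera adjusted p = 0.0073; adjusted p = 0.436 with an estimated correlation). The cell wall list had a median of 0.30 with 1 of 29 higher, the glucanase BGL2 (0.59 ± 0.10), and 6 when adjusted over the list alone (camera adjusted p = 0.00161, and 0.436 with an estimated correlation). On array 1 the median of this list was -0.13. The proteasome (median 0.19, adjusted p = 0.0032) and methionine and sulfur genes (0.23, adjusted p = 0.0105) were higher as lists with 0 of 29 members past the threshold in each, and had an adjusted p = 0.66 and 0.436 with an estimated correlation. In the pentose phosphate pathway 1 of 10 genes, NQM1, was lower, or 2 higher and 1 lower when adjusted over the list alone (median 0.19, camera adjusted p = 0.726). ZWF1, the glucose 6-phosphate dehydrogenase, was at 0.86 ± 0.21 (adjusted p = 0.0736). In acetate metabolism 1 of 8, ACH1, was higher, or 3 when adjusted over the list alone (median 0.50, adjusted p = 0.0815). ALD6, the cytosolic aldehyde dehydrogenase, was at -0.42 ± 0.56.

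The remaining lists did not pass over the 5 arrays. For ergosterol, G1/S and mating genes the difference between the sets passed by camera, as given below, and did not with an estimated correlation (adjusted p = 0.551 each). These lists were ergosterol (median 0.04, 2 of 23 higher and, adjusted over the list alone, 5 higher and 1 lower, adjusted p = 0.119), histones (-0.11, adjusted p = 0.436), purine and one-carbon synthesis (0.11, with a mean just below 0, adjusted p = 0.744) and G1/S cell cycle (0.01, adjusted p = 0.744, with camera pointing lower). Mating and filamentation (-0.03, with a mean of 0.12 and camera pointing higher, adjusted p = 0.54) was a further one. Markers of stationary phase cells carried over from the overnight culture, at a median of 0.15 with 1 of 17 lower, FMP45 (-0.84 ± 0.10), did not pass either (adjusted p = 0.726). Adjusted over the list alone, 3 of these markers were higher and 4 lower, and 1 gene was higher and 1 lower in both the purine and the mating list. In all, 12 lists were higher and 3 lower by camera with the preset correlation, 3 of 26 passed by fry, and 0 passed with an estimated correlation. Those by fry are ribosome biogenesis (adjusted p = 0.0405), methionine and sulfur genes (adjusted p = 0.0405) and acetate metabolism (adjusted p = 0.0471), which did not pass by camera.

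Some list calls depend on the fit. With the set of arrays as a term 12 lists passed. The calls of the Msn2/Msn4 (adjusted p = 0.0512), gluconeogenesis (0.0512), translation factor (0.0509) and trehalose lists (0.0873) ended, and the osmostress list passed as lower (median -0.19, adjusted p = 0.0118). Without replicate 2 the calls of the oxidative stress (0.111), translation factor (0.115), proteasome (0.171), Msn2/Msn4 (0.0804) and trehalose lists (0.241) ended, and the osmostress list passed (median -0.38, adjusted p = 0.0278). Without replicate 3 those of the gluconeogenesis, translation factor and trehalose lists ended (adjusted p = 0.102 each). The gluconeogenesis call also ended without replicate 4 (0.0551) and without replicate 5 (0.0705). Acetate metabolism passed without replicate 4 (0.0236) and without replicate 5 (0.00645). Without replicate 5, G1/S (median -0.27, adjusted p = 0.013), ergosterol (0.17, adjusted p = 0.0125) and ribosomal proteins (-0.08, adjusted p = 0.0107) passed too. In each of these fits 0 lists passed with an estimated correlation (smallest adjusted p = 0.38, without replicate 4).

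**Figure D2:**
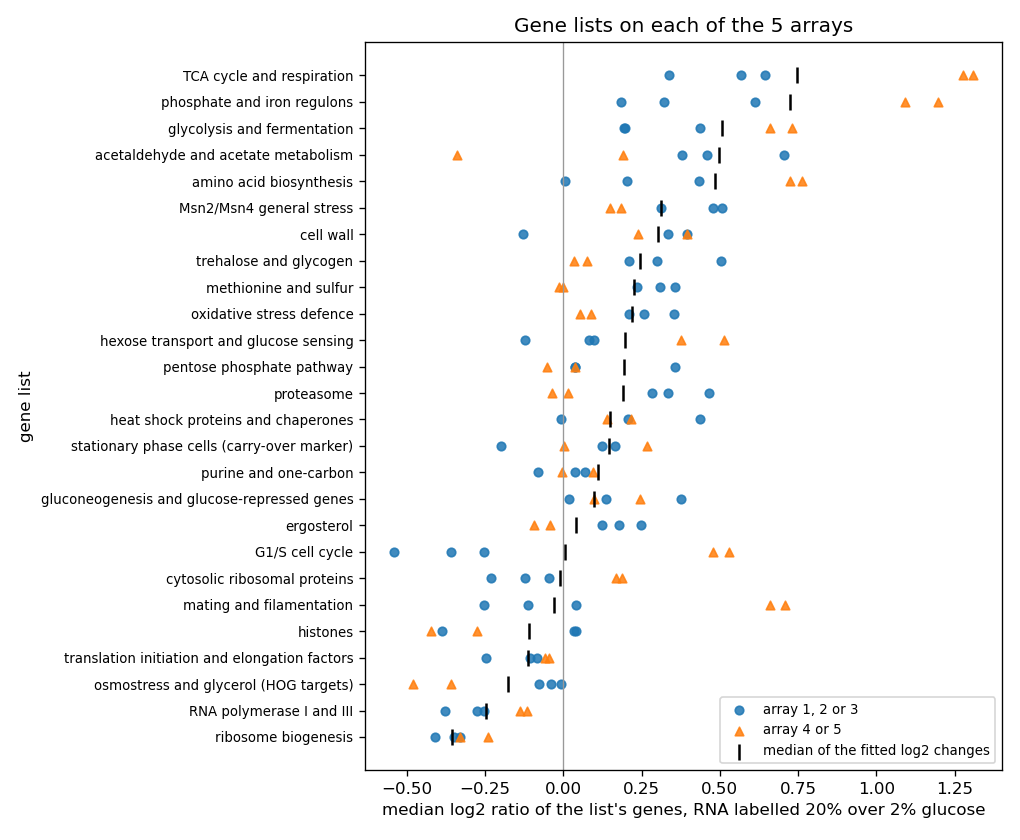
Median log2 ratio of RNA labelled 20% over RNA labelled 2% glucose (horizontal axis) of the tested genes of each list (vertical axis) on arrays 1 to 3 (circles) and arrays 4 and 5 (triangles), with the median of the fitted changes as a black bar. Ribosome biogenesis lies below 0 on 5 of 5 arrays, and G1/S cell cycle genes lie below 0 on arrays 1 to 3 and above 0 on arrays 4 and 5.

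Arrays 1 to 3 and arrays 4 and 5 differed, among others in the size of the change of osmostress genes. GPD1 was at -2.07 ± 0.33 (SD, n = 3) on arrays 1 to 3 and at -6.70 ± 0.26 (SD, n = 2) on arrays 4 and 5, 4.21-fold against 104-fold, with an adjusted p of 0.00102 for the difference in limma. STL1 was near 0 on arrays 1 and 3 (-0.10 and 0.08) and at -6.66 and -5.64 on arrays 4 and 5 (adjusted p = 0.00165). RTC3 was at -2.11 ± 0.53 (SD, n = 3) on the first set; on the second it was at least 28.1-fold lower in the RNA labelled 20%, where its spot was not well above background. HSP12 went the other way, at -4.17 ± 0.82 (SD, n = 3) on arrays 1 to 3 and -0.90 ± 0.11 (SD, n = 2) on arrays 4 and 5 (adjusted p = 0.0101). ALD6 changed sign, from 0.71 ± 0.07 (SD, n = 3) to -1.99 ± 0.03 (SD, n = 2) (adjusted p = 0.00175).

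The difference between the sets passed the threshold for 696 genes, 360 with a higher ratio on arrays 4 and 5 and 336 with a lower one. It passed for 11 lists by camera with the preset correlation and 0 with an estimated one, where the smallest adjusted p = 0.551. The G1/S cell cycle list had a median of -0.47 with 10 genes lower on arrays 1 to 3 and of 0.66 with 14 higher and 1 lower on arrays 4 and 5 (adjusted p = 1.28e-07). TCA cycle and respiration genes were higher in each, at medians of 0.48 and 1.33 (adjusted p = 2.16e-12). So were amino acid biosynthesis genes, at 0.24 and 0.74 (adjusted p = 1.28e-07), although their median on array 1 was 0.006. Glycolysis and fermentation had medians of 0.30 and 0.88 (adjusted p = 0.00168), ribosomal proteins -0.13 and 0.17 (adjusted p = 1.54e-08), the proteasome 0.36 and -0.01 (adjusted p = 1.86e-05) and mating genes -0.22 and 0.64 (adjusted p = 3.68e-05). The osmostress list had medians of -0.12 and -0.45 (adjusted p = 0.00207), ergosterol 0.19 and -0.11 (adjusted p = 0.0159), RNA polymerase I and III -0.31 and -0.14 (adjusted p = 0.039) and the phosphate and iron regulons 0.33 and 1.29 (adjusted p = 0.0352). Ribosome biogenesis, at -0.37 and -0.30, was not shown to differ (adjusted p = 0.104).

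Fitted alone, arrays 1 to 3 gave 593 genes higher and 308 lower of 5164, and arrays 4 and 5 gave 1496 and 1428 of 5371. Of the genes tested in each, 575 were called in both sets. The sign was the same for 451, where lists drawn independently would share 230.57, and opposite for 124, where 228.75 are expected. Correlations across genes, which are not independent replicates, were 0.597 to 0.861 between pairs of arrays 1 to 3, 0.951 between arrays 4 and 5, and 0.256 to 0.374 across the sets. With the set as a further term the fit called 894 genes higher and 724 lower, including all 201 genes above. Of the 38 named genes, 36 passed in this fit and 26 over the 5 arrays without it. The 10 that passed only with the term are GPD1 (adjusted p = 2.83e-05), STL1, RTC3, HSP12, CTT1, HXT7 (0.00352), TDH1 (0.0117), ZWF1 (0.00208), NSR1 (0.0233) and ALD6 (0.00208), whose sign differs between the sets. The estimate of this fit averages the sets, so passing does not show a change in each. STL1 was near 0 on arrays 1 and 3 (-0.10 and 0.08), and CTT1 was at -0.21 ± 0.22 (SD, n = 3) on arrays 1 to 3.

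**Figure D3:**
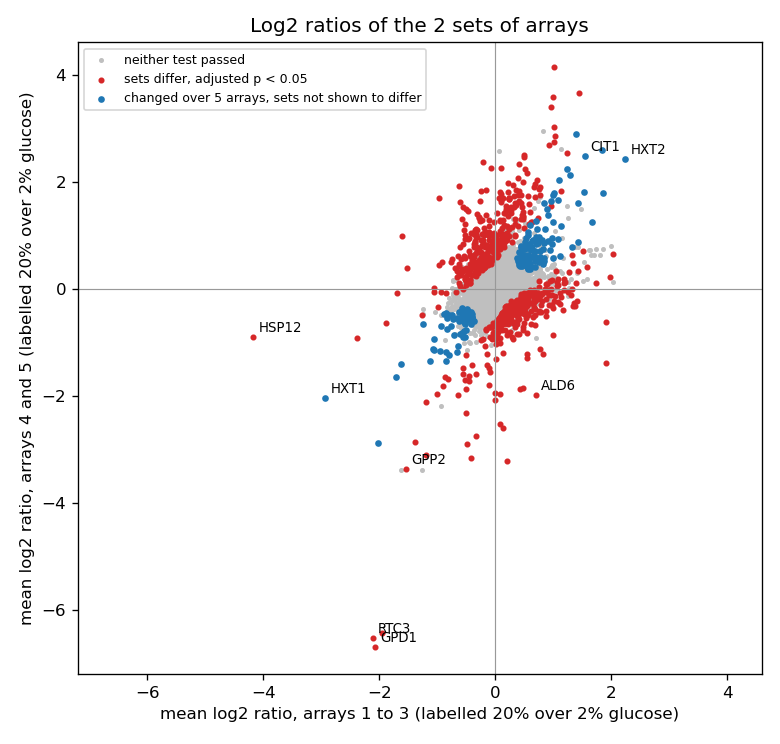
Mean log2 ratio on arrays 1 to 3 (horizontal axis) against arrays 4 and 5 (vertical axis), RNA labelled 20% over RNA labelled 2% glucose, for the 4693 genes with all 5 values. Red points (654) passed the test of the difference between the sets, and blue points (177) were called over the 5 arrays without a difference shown between the sets.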

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

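The test of the difference between the sets and the fit with the set as a term were planned, while the other tests in the next 2 paragraphs were chosen after the results were seen, or amended then: the comparison on bright spots was written first, but its interval was added once its value was known.

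The markers that ran against the dye labels form the first pattern: from the 18 genes fixed beforehand, 14 were given a textbook direction under stress or high glucose after the values were seen, and 12 of these had the opposite sign by the labels, FBP1 among them at close to 0, while HSP104 and TSL1 had the textbook sign (past the threshold, 5 opposed and 1 followed the labels, and 11 and 1 with the set of arrays as a term). A candidate explanation is that the dye labels are exchanged on all 5 arrays, and list medians run both ways. Those of TCA cycle and respiration (0.75, 47 of 47 positive), gluconeogenesis (0.10) and osmostress (-0.18) run as exchanged labels would give. Those of Msn2/Msn4 (0.31), heat shock (0.15), oxidative stress (0.22), trehalose (0.24) and ribosome biogenesis (-0.36) run as a stress response by the labels would. Glycolysis (0.51, 19 of 20 positive) runs as a glucose response by the labels would. Whether high glucose moves the stress and ribosome lists the same way as stress was not examined, so they decide little. The stress lists also share members such as HSP104 and CTT1. HXK1, a marker counted as opposing the labels, is a called member of the Msn2/Msn4 and glycolysis lists. On arrays 4 and 5 the 4 stress lists do not pass by camera (adjusted p = 0.347, 0.133, 0.657 and 0.698), while glycolysis (2.19e-08) and ribosome biogenesis (7.91e-11) do. On arrays 1 to 3 these 4 pass as higher (0.000462, 0.0105, 0.00626 and 0.000991), and their difference between the sets does not pass (0.137, 0.727, 0.152 and 0.114). The osmostress list passes as lower (0.0159 and 0.0286) and TCA cycle and respiration as higher (1.14e-12 and 4.44e-18) in each set. With an estimated correlation 0 lists pass in either set or over the 5 arrays. On arrays 1 to 3, 9 markers past the threshold opposed the labels and 1 followed them (12 opposed by sign, STL1 and FBP1 close to 0). On arrays 4 and 5, 11 opposed and 2 followed. The glucose-induced MIG2 and MIG3 opposed them on arrays 1 to 3 (-1.61 and -1.52) and followed them on arrays 4 and 5 (0.99 and 0.39). These counts cannot say whether labels are exchanged in only 1 of the sets. The direction of arrays 1 to 3 was taken from the other columns and not from their own dye labels, so there the markers show only a shared direction of most columns' values. A table turned the wrong way for arrays 4 and 5 is argued against, since its direction was set by the scanner ratios (correlations 0.991 and 0.964). In the scanner values 11 markers opposed the labels, which follows from that alignment and adds no separate evidence. Exchanged labels and a real response that is opposite for part of the genes both stay open.

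The split between arrays 1 to 3 and arrays 4 and 5 is the second pattern: 696 genes, 11 lists and 16 of the 38 named genes differed between the sets by the test of the difference, and 0 lists with an estimated correlation (smallest adjusted p = 0.551). The authors' normalization of arrays 4 and 5 and dye bias are argued against as the cause. With scanner intensities normalized anew the set means correlated at 0.369 across genes (0.38 with the table). Arrays of 1 orientation in different sets correlated at 0.374 at most, under the lowest correlation of 0.597 within arrays 1 to 3. The value of 0.369 was nearly fixed in advance, since the repaired table follows the scanner ratios (correlations 0.991 and 0.964). That close match is itself what argues against the normalization of arrays 4 and 5. The authors' processing of arrays 1 to 3 was not examined and stays open. Noise of dim spots that is independent on each array is argued against as the main cause. It would lower the correlations within the sets too, but these were 0.597 to 0.861 and 0.951, against 0.256 to 0.374 across the sets. Whether dim spots add to the split stays open. Among the brightest 1174 genes the set means correlated at 0.561, which alone lies under 0.597. These are unlike measures, since 0.597 is between single arrays over all genes and a mean of arrays carries less noise. The bootstrap interval added afterwards, 0.486 to 0.626, includes 0.597. In a further comparison 11.8% of these genes and 14.6% of the others passed the test of the difference. The real split, fitted without a dye term, called 1172 genes and the highest of the other splits 0, and 10 splits, of which 1, the real one, gave as many, are too few for a share under 0.05. No biological explanation was tested, since the labels of the sets are alike.

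A single array stood apart from the other 4 for 8 of 62 values tested, where chance gives about 1 in 20, or 3.1. The gap to the nearest array as a share of the whole range was 0.791 for HXT2 (array 2 lowest), 0.737 for GAP1 (array 3 highest), 0.847 for PUT1 (array 1 lowest), 0.798 for GGC1 (array 1 lowest), 0.758 for NCA3 (array 2 lowest), 0.717 for HXK1 (array 1 highest), 0.899 for NSR1 (array 3 lowest) and 0.779 for the median of the pentose phosphate pathway (array 2 highest). Each of the 7 genes kept its sign on every array.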

How the results depend on the processing

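Exchanged dye labels, the table without the decimal repair and the averaged arrays were chosen after seeing the data; the other alternatives were planned. The 122 genes higher and 79 lower, and the 15 lists, stayed within 1.5 times under median centring, scaling, robust moderation, 1 spot per gene, genes on 3 or more arrays, and scanner values for arrays 4 and 5. Requiring all 5 values gave 120 lower, in 4693 genes. The genes higher and lower were 463 and 456 with no dye term, 218 and 162 with array weights, 894 and 724 with the set of arrays as a term, 593 and 308 on arrays 1 to 3 alone, 1496 and 1428 on arrays 4 and 5 alone, and 225 and 152 with arrays 4 and 5 averaged as 1. They were 1604 and 1536 with the scanner files alone, 1698 and 1634 there with no background subtraction, and 1605 and 1532 without dim spots. They were 1 and 1 with 20% glucose in Cy3 alone, 0 and 0 with 20% in Cy5 alone, 1 and 0 with decimals as deposited, 2 and 2 at an adjusted p under 0.01, 28 and 20 with a log2 change of 1 or more, and 79 and 122 with the dye labels exchanged. Leaving out 1 replicate gave 0 to 67 higher and 0 to 36 lower. At these settings none of the 201 genes changed sign where tested, the exchange of labels apart. Since all 201 had the same sign on every array with a value, this was nearly fixed in advance for fits of the table's values. It is therefore no support for the calls. Camera with an estimated correlation called 0 lists and fry 3. The causes were not tested.

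The following values turned sign. ALD6 (-0.42) was at 0.69 on arrays 1, 2 and 3 alone, 0.0338 with arrays 4 and 5 averaged, and -1.08 to 0.24 without 1 replicate. FBP1 (0.025) was at -0.00353 with scanner values for arrays 4 and 5, -0.0774 with the scanner files alone, -0.0843 there with no background subtraction, -0.0774 without dim spots, -0.0097 on arrays 4 and 5 alone, -0.042 with 20% in Cy5 alone, and -0.0535 to 0.0836 without 1 replicate. The median of the ribosomal proteins (-0.0111) was 0.000116 with scanner values for arrays 4 and 5, 0.184, 0.18 and 0.186 in the scanner files (alone, with no background subtraction, without dim spots), 0.0202 with the set as a term, 0.167 on arrays 4 and 5 alone, 0.037 with 20% in Cy5 alone and -0.0816 to 0.0709 without 1 replicate. That of mating and filamentation (-0.0313) was 0.164 with all 5 values, 0.581, 0.504 and 0.581 in the scanner files, 0.0856 with the set as a term, 0.636 on arrays 4 and 5 alone, 0.195 with 20% in Cy5 alone and -0.0584 to 0.266 without 1 replicate. That of ergosterol (0.0412) was -0.0924, -0.0849 and -0.0924 in the scanner files, -0.112 on arrays 4 and 5 alone and -0.00828 to 0.173 without 1 replicate. That of the proteasome (0.192) was -0.0111, -0.00576 and -0.0111 in the scanner files, -0.00525 on arrays 4 and 5 alone and 0.0871 to 0.292 without 1 replicate. G1/S (0.0051) was at -0.0178 with array weights, -0.472 on arrays 1, 2 and 3 alone, -0.0846 with arrays 4 and 5 averaged and -0.271 to 0.224 without 1 replicate. On arrays 4 and 5 alone the pentose phosphate pathway (0.193) was at -0.0294 and acetaldehyde and acetate metabolism (0.496) at -0.264. Without 1 replicate these were at 0.0465 to 0.231 and 0.361 to 0.492, and histones (-0.11) at -0.209 to 0.0164.

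Spots near background limit the ratios of arrays 4 and 5: under the 20% label RTC3 was under 2 times background on both arrays and HXT1 on array 5, and signal over background of arrays 1 to 3 was not analysed here.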

Other observations

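Several genes of nitrogen and nucleotide metabolism outside the lists, chosen after their values were seen, were higher in the RNA labelled 20% on 5 of 5 arrays and past the threshold in limma. They were picked for being higher and not tested as a group, so they show no shift of such genes as a whole. The amino acid permeases AGP1 (1.13 ± 0.15 SE, adjusted p = 0.0397) and DIP5 (1.08 ± 0.12, adjusted p = 0.0306) accompanied GAP1, as did the arginase CAR1 (0.60 ± 0.10, adjusted p = 0.043) and ARO10 of aromatic amino acid breakdown (1.16 ± 0.19, adjusted p = 0.043). Of the ribonucleotide reductase subunits, RNR2 (1.20 ± 0.14), RNR3 (0.63 ± 0.09) and RNR4 (1.16 ± 0.09) were higher. RNR1, whose transcript peaks at G1/S, is a member of the G1/S list and part of that list's result above. It was at -0.52 on arrays 1 to 3 and 0.99 on arrays 4 and 5 (adjusted p = 0.00771 for the difference in limma).

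Further genes chosen after their values were seen went opposite ways in the sets, each past the test of the difference. The glucose-induced repressors MIG2 (-1.61 and 0.99) and MIG3 (-1.52 and 0.39) and the replication genes POL30 (-0.51 and 1.20) and POL1 (-0.39 and 1.03) were lower in the RNA labelled 20% on arrays 1 to 3 and higher on arrays 4 and 5. MIG2 and MIG3 are members of the hexose transport list, and POL30 and POL1 of the G1/S list. FRE7, a metal reductase (1.91 and -1.40), and PIL1 of the eisosomes (0.48 and -1.85) went the other way. Among 58 processes annotated in the scanner files with at least 10 genes, chosen after the data were seen, camera found 6 higher and 6 lower over the 5 arrays, and 10 that differed between the sets, among them DNA replication initiation (medians -0.07 and 0.22, adjusted p = 0.0285). With an estimated correlation 0 processes passed either test (smallest adjusted p = 0.694 and 0.881).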
